A study of Pseudotsuga menziesii with 26 samples.

How the data were processed

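The data were poly(A) RNA sequencing libraries from previous-year needles of Douglas-fir seedlings, 26 in all, from 4 groups (Air Control n = 6, DE n = 7, DECe n = 7, DECe Gas Phase n = 6). Groups came from the source label of each sample and replicate numbers from its title. Per the labels' protocols, messenger RNA was isolated from total RNA with FastTrack MAG kits and libraries were made with PrepX kits for Illumina sequencing on an automated system, and each atmosphere had 1 exposure chamber of 984 L with 16 h of light at 280 µmol per second and square metre. Seedlings were separate plants assigned to the groups at random, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2. The aligner, the counting tool, the reference transcriptome and the treatment of reads that match several transcripts are not given in the sources used here, so transcripts that share reads with a near-identical copy cannot be told from it, and strand is not stated.

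The deposited count table holds raw counts per transcript and library, per the file headers, as whole numbers over 173882 transcripts. Of these, 80100 were at 0 in all libraries, and no row lacked an identifier. The deposited RPKM table holds, per the file headers, reads per kilobase of transcript and per 1000000 counts of the library. Dividing the counts by the RPKM values gave 1 length per transcript, within 0.00835% at RPKM of 10 or more, so the authors' RPKM used the column total of the count table. Those implied lengths are the lengths printed here. No column of the tables was left out. No reference genome or name table was used, and the files do not pair identifiers with names. The tests of gene lists fixed before the data were examined were therefore not run, and by the rule fixed for that case the transcripts named are, per comparison, those with the largest change in each direction (2 higher and 2 lower) among transcripts with an adjusted p under 0.05 and a median of at least 1 CPM in the higher group, or the smallest p-values where fewer than 10 passed. Transcripts outside the rule are said to be singled out.

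The main test was edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with filterByExpr by group (minimum count 10), TMM factors, 1 model over all 26 libraries with the 4 groups, a trended dispersion, robust quasi-likelihood F tests and Benjamini-Hochberg adjustment within each comparison, at an adjusted p under 0.05. It tested 26942 transcripts. The SE printed with an edgeR log2 fold change is that change divided by the signed square root of its F statistic. It is not an error that edgeR itself reports. CPM values in the text are counts per 1000000 of the TMM-scaled library size. Distances between libraries were Euclidean on log2 CPM with a prior count of 2 and were tested by permuting the group labels (R2, the share of squared distances between groups), with 100000 permutations for the 4 groups and every split of the libraries for pairs. Totals, detected transcripts and counts outside the dominant transcripts were compared by exact permutation tests and library classes by exact tests on counts, each adjusted over 5 comparisons. The edgeR, limma-voom, limma and DESeq2 steps were tested on simulated counts with 200 changed transcripts. The simulated libraries kept the scaled sizes of the real ones but shared 1 profile, so they held no narrow composition. Changes were placed only in transcripts above a minimum mean count. Recovery in the real libraries could therefore be lower than simulated. The distance step was tested on simulated normal values with and without a shift between groups. In the DECe and Air Control simulation (26942 transcripts), edgeR recovered 15% of those changed 4-fold and 95% of those changed 16-fold, with 4 false calls among 114, and with the broad libraries alone (45063 transcripts) 53% and 97%. In the DE and Air Control simulation (26942 transcripts) it recovered 9% and 71%, with 15 false calls among 95.

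Total counts ran from 2467403 to 60457187 per library. A floor of 3 counts stands for a count of 0, which came to 0.0127 CPM in DECe replicate 3 and 7.19 CPM in DE replicate 4 after scaling. Intervals for shares are 95% exact (Clopper-Pearson) binomial intervals. Reads carried no molecular identifiers that the sources name, so intervals and floors cover counting error only. No pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom 51.8 within groups), so each counted as 1 replicate.

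The alternatives fixed before the data were examined were DESeq2's size factors (RLE), library sizes alone, no filter on low counts, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom (limma 3.58.1) with sample quality weights, a fit that is not robust, the replicate number as a block, limma on log2(RPKM + 1) and log2(RPKM + 0.1), a fit on the 2 groups compared, and leaving out each library in turn, and for distances also Spearman correlations and the 2000 most variable transcripts. Added after the data were examined were the broad libraries alone, the narrow libraries alone, log10 of the counts outside the dominant transcripts as a covariate, removal of the dominant transcripts, thinning of the other counts to the lowest library and edgeR with legacy=FALSE. Library class, dominant transcripts (above 1% of the counts in any library) and narrow markers were also defined then. Other splits of the libraries were drawn 40 at a time with a fixed seed, the real one included. Measurements of the chamber air and of cerium on needles are not used here.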

Results

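Poly(A) RNA was sequenced from the previous year's needles of Douglas-fir (Pseudotsuga menziesii) seedlings that shared 1 parent, giving 26 libraries, 1 per seedling. The seedlings had been kept for 2 weeks in exposure chambers and received the test atmosphere for 6 h a day on 5 days a week. The Air Control group (n = 6) received filtered air. The DE group (n = 7) received exhaust from a diesel engine, and the DECe group (n = 7) received exhaust from diesel fuel carrying cerium dioxide (CeO2) nanoparticles as a catalyst. The DECe Gas Phase group (n = 6) received the DECe exhaust after a particle filter. Each atmosphere had 1 chamber, so the p-values measure the spread between seedlings within chambers and cannot separate an atmosphere from its chamber. Transcripts carry identifiers that the files do not pair with gene names, so the transcripts below are given by identifier and by the length implied by the deposited RPKM values, without a function.

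The total count per library ran from 2467403 in DE replicate 8 to 60457187 in DECe replicate 3. A small set of transcripts took most of the counts in many libraries. The set of 23 transcripts that passed 1% of the counts in at least 1 library, called dominant transcripts here, took between 33.6% of the counts in Air Control replicate 5 and 95.8% in DE replicate 4. The most abundant, psme_t002753 (4295 nt, singled out after its values were seen), held 12.8% ± 5.98 of the counts in Air Control (SD, n = 6) and 38.5% ± 13.9 in DE (SD, n = 7). It held 26.9% ± 18.9 in DECe (SD, n = 7) and 24.8% ± 20.3 in DECe Gas Phase (SD, n = 6).

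Outside the dominant transcripts, the libraries fell on either side of a wide gap. In 15 libraries, called broad here, between 5950200 and 33757303 counts remained. In the other 11, called narrow, between 151321 and 879616 remained. This division, at 1000000 counts, was made after the data were examined and does not use the groups. The count it uses depends on total depth as well as on library composition. Total counts were 2467403 to 9017951 in the narrow libraries and 12404373 to 60457187 in the broad ones. By the share of the dominant transcripts the classes lay close together, at 33.6% to 81.8% in the broad and 84.7% to 95.8% in the narrow libraries. The highest broad share was that of Air Control replicate 14, which had 43560508 counts, so its class rests on its depth. The narrow libraries were 6 of 7 in DE, 3 of 7 in DECe, 2 of 6 in DECe Gas Phase and 0 of 6 in Air Control. The distribution over the 4 groups differed by an exact test of class by group (p = 0.0153, two-sided). DE differed from Air Control by Fisher's exact test (p = 0.00466, adjusted p = 0.0233 over the 5 pairs of groups), and the other 4 pairs did not pass, with adjusted p between 0.443 and 1. The geometric mean count outside the dominant transcripts in DE was 0.0355 times that in Air Control (exact permutation test, two-sided, p = 0.00233, adjusted p = 0.0117, n = 7 and 6). It was 0.214 times that in Air Control in DECe and 0.272 times in DECe Gas Phase, and neither these nor the other pairs passed (exact permutation tests, adjusted p between 0.131 and 0.822). The total count was 0.210 times that in Air Control in DE (exact permutation test, two-sided, adjusted p = 0.00874) and 0.434 times in DECe Gas Phase (exact p = 0.0152, adjusted p = 0.0379), and the other 3 pairs did not pass (adjusted p between 0.0874 and 0.830). DE detected fewer transcripts than Air Control, 17435 ± 18282 against 51271 ± 7314 (SD, n = 7 and 6, exact permutation test, two-sided, adjusted p = 0.0262), and the other 4 pairs did not pass (adjusted p between 0.137 and 0.567). The broad libraries detected 36286 to 62480 transcripts and the narrow ones 6049 to 25382.

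**Figure D1:**
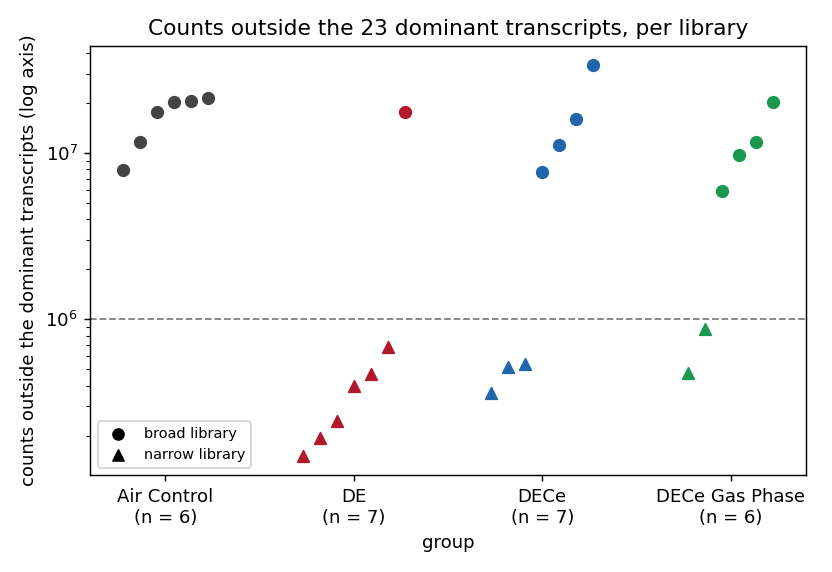
Counts outside the 23 dominant transcripts in each library (log axis) by group, with circles for broad and triangles for narrow libraries and a dashed line at 1000000 counts. All 6 Air Control libraries lie above the line and 6 of the 7 DE libraries lie below it.

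Narrow libraries also held transcripts that were scarce in the broad ones. For 31 transcripts, the pooled level was above 100 CPM (counts scaled to a library of 1000000) in the narrow libraries and over 20 times that in the broad ones. Together these narrow markers took 10.9% ± 5.03 of the counts in DE (SD, n = 7) and 0.0264% ± 0.0135 in Air Control (SD, n = 6). They took 4.61% ± 5.68 in DECe (SD, n = 7) and 2.31% ± 5.00 in DECe Gas Phase (SD, n = 6), where single libraries ran from 0.0132% (95% exact binomial interval 0.0127% to 0.0136%) to 12.5% (12.5% to 12.5%). DECe Gas Phase replicate 4 was the exception among the narrow libraries, at 0.0320% (0.0306% to 0.0334%), and its most abundant transcript was psme_t000146 (8738 nt, singled out after its values were seen) at 39.6% of the counts. In Air Control replicate 14, a broad library, psme_t000146 was also the most abundant, at 32.3%. The first principal component of normalized log2 CPM, with 52.4% of the variance, separated the narrow from the broad libraries.

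**Figure D2:**
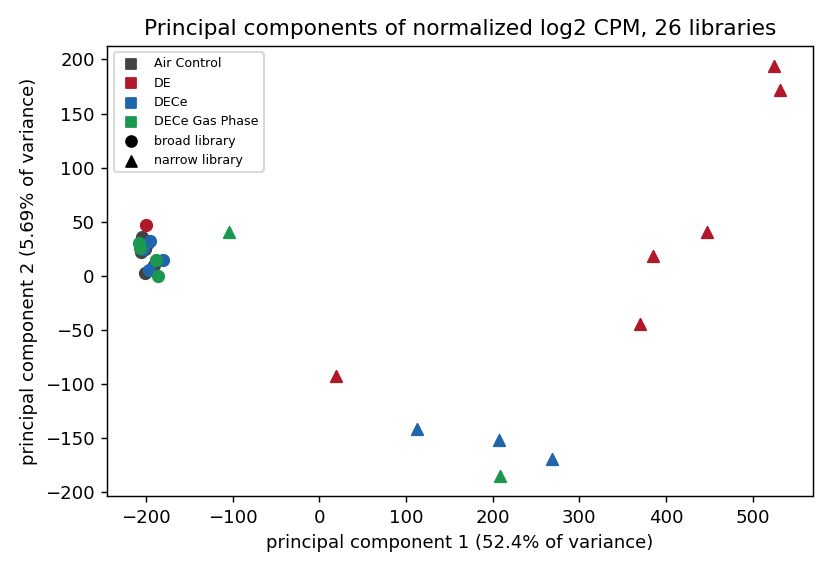
First 2 principal components of normalized log2 CPM of the 26 libraries, with colours for the groups, circles for broad and triangles for narrow libraries. Component 1 carries 52.4% of the variance and component 2 carries 5.69%, and all 15 broad libraries cluster at the left of component 1.

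The first comparison asked which needle transcripts differ after whole diesel exhaust. Between DE and Air Control, 2263 of the 26942 tested transcripts changed, 1149 higher and 1114 lower in DE (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among the higher ones, psme_t133486 (402 nt) reached 97.0 ± 116 CPM in DE (SD, n = 7) and had 0 counts in all 6 Air Control libraries. At a floor of 3 counts per library, up to 0.0914 CPM in Air Control, its mean was at least 1060-fold higher after TMM scaling (edgeR adjusted p = 0.0273). Likewise, psme_t029573 (1520 nt) reached 90.9 ± 88.6 CPM in DE (SD, n = 7), at least 994-fold above that floor (edgeR adjusted p = 0.0199). The TMM factors were 0.0614 to 0.351 in the narrow DE libraries and 0.754 to 4.01 in Air Control. They raise the DE levels relative to Air Control, so both folds hold for this scaling only. The first call ended without Air Control replicate 5 or 11 (edgeR adjusted p = 0.0517 and 0.0528) and in 3 of 15 other alternatives (adjusted p up to 0.376), and the second in 2 of 15 (up to 0.338). Both had counts in 6 of the 7 DE libraries, the narrow ones, and 0 counts in DE replicate 5, the broad one. The narrow markers, whose choice by library class fixes this direction, had a median log2 fold change of 13.13 in DE (30 of 31 past the threshold). Against Air Control the median was also high in DECe, at 10.58 (lowest 6.16), and in DECe Gas Phase, at 8.12 (lowest 5.55), with 0 of 31 past the threshold in each (edgeR).

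The transcripts that fell most in DE were psme_t094707 (530 nt), at 1.23 ± 0.554 CPM in Air Control (SD, n = 6), and psme_t021809 (1893 nt), at 1.20 ± 1.01 CPM (SD, n = 6). Both had 0 counts in all 7 DE libraries (edgeR adjusted p = 0.00517 and 0.0177). Without DE replicate 5 both calls ended (edgeR adjusted p = 0.0595 and 0.151), as did the first in 3 of 14 other alternatives and the second in 6 of 15. The floor of 3 counts was 0.0239 CPM in DE replicate 5 and 1.06 CPM in DE replicate 12. In the other 5 DE libraries it was 3.91 to 7.19 CPM, above the highest Air Control levels of 2.30 and 2.92 CPM, so the levels seen in Air Control were not detectable there. In the limma-voom alternative with sample quality weights, psme_t021809 lay on the other side, at a log2 fold change of 0.60 (adjusted p = 0.703, against 0.00111 to 0.703 over its alternatives). With the tested transcripts parted by mean count into 3 classes of nearly equal size, 664 higher and 133 lower transcripts were in the low class, 230 and 128 in the middle class, and 255 and 853 in the high class.

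Library class moved with this comparison. With the broad libraries alone, where DE has 1 library, 27 transcripts changed, 25 higher and 2 lower, of which 7 were among the 2263, and that single DE library was assumed to vary like the other groups. With the count outside the dominant transcripts as a covariate, 31 changed, 12 higher and 19 lower. The split depended on the scaling, with 1383 higher and 468 lower under DESeq2's size factors. The median log2 fold change over all tested transcripts was -0.51 with TMM scaling, -0.17 with those size factors and -2.0035 with library sizes alone, and the changes above are relative to the first.

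The second comparison asked the same of exhaust from the CeO2 fuel. Between DECe and Air Control, 41 transcripts changed, 19 higher and 22 lower in DECe (edgeR, adjusted p under 0.05). The count fell to between 2 and 6 without Air Control replicate 5, 8, 11, 14 or 15, to 24 without Air Control replicate 3 and to 14 without DECe replicate 4. It was 4 in edgeR with legacy=FALSE and 4 after thinning to the lowest library, and DESeq2 gave 966. The 405 nt transcript psme_t132144 fell most. It was at 3.53 ± 5.43 CPM in Air Control (SD, n = 6), with counts in all 6 libraries, and at 0.00458 ± 0.00806 CPM in DECe (SD, n = 7), where 5 of 7 libraries had 0 counts. In the 3 narrow DECe libraries the floor of 3 counts was 0.941 to 2.75 CPM, above the lowest Air Control level of 0.640 CPM, so such a level was not detectable there. Its log2 fold change was -8.18 ± 1.32 (SE, edgeR adjusted p = 0.0234, against at most 0.0428 over its alternatives). The other lower transcript named by the rule, psme_t068173 (709 nt), went from 1.37 ± 1.10 CPM in Air Control (SD, n = 6) to 0.0621 ± 0.0697 CPM in DECe (SD, n = 7), a log2 fold change of -3.80 ± 0.76 (SE, edgeR adjusted p = 0.0352, against 8.23e-04 to 0.560 over its alternatives). That call ended in 5 of 13 cases when 1 library was left out and in 5 of 15 other alternatives, with the direction kept.

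Of the transcripts higher in DECe, psme_t031938 (1426 nt) was at 8.28 ± 10.4 CPM against 0.572 ± 0.363 CPM in Air Control (SD, n = 7 and 6), a log2 fold change of 3.88 ± 0.81 (SE, edgeR adjusted p = 0.0420). The 353 nt transcript psme_t158514 was at 2.85 ± 3.32 CPM against 0.263 ± 0.165 CPM (SD, n = 7 and 6), a log2 fold change of 3.60 ± 0.76 (SE, edgeR adjusted p = 0.0396). The calls of both rising transcripts were close to the threshold. Leaving out 1 library at a time ended the first in 9 of 13 cases and the second in 8 of 13, with the direction kept. The broad libraries alone (4 against 6) gave 57 changed transcripts, 27 higher and 30 lower, and 17 of these were among the 41. The narrow libraries hold no Air Control library, so they give no value. With library sizes alone as the scaling, 560 were higher and 6 lower, and with the covariate 86 changed, 35 higher and 51 lower.

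**Figure D3:**
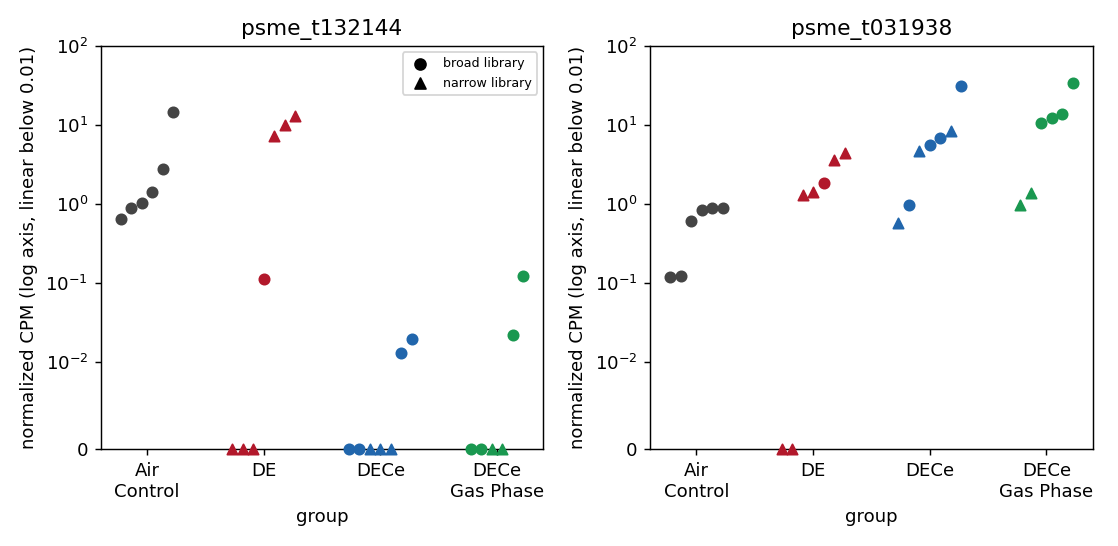
Normalized CPM (log axis, linear below 0.01) of psme_t132144 and psme_t031938 in each library by group, with circles for broad and triangles for narrow libraries. All 6 Air Control libraries hold psme_t132144 at 0.640 CPM or more and the broad DECe and DECe Gas Phase libraries at 0.120 CPM or less, the narrow ones of both groups have 0 counts with floors of 0.690 to 2.75 CPM, and psme_t031938 is at most 0.878 CPM in Air Control.

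A further comparison set the particle-filtered exhaust against air. Between DECe Gas Phase and Air Control, 16 transcripts changed, 12 higher and 4 lower in DECe Gas Phase (edgeR, adjusted p under 0.05). Of the 4 transcripts named for DECe, 3 were named here too. The level of psme_t031938 was 12.1 ± 11.98 CPM in DECe Gas Phase (SD, n = 6), a log2 fold change of 4.42 ± 0.84 (SE, edgeR adjusted p = 0.0310), and psme_t158514 was at 3.06 ± 2.44 CPM (SD, n = 6), a log2 fold change of 3.64 ± 0.77 (SE, edgeR adjusted p = 0.0452). The count ran from 1 without Air Control replicate 3 or 5 or DECe Gas Phase replicate 2 to 79 without DECe Gas Phase replicate 5, and DESeq2 gave 605. It was 0 in edgeR with legacy=FALSE, where 1190 transcripts had an unadjusted p under 0.05, and 0 in edgeR after thinning to the lowest library, where 345 of 3202 did. On the lower side, psme_t132144 was at 0.0236 ± 0.0480 CPM (SD, n = 6), a log2 fold change of -6.93 ± 1.25 (SE, edgeR adjusted p = 0.0310). The 1857 nt transcript psme_t022430 was at 0.0387 ± 0.0345 CPM against 1.01 ± 0.668 CPM in Air Control (SD, n = 6 and 6), a log2 fold change of -4.21 ± 0.86 (SE, edgeR adjusted p = 0.0422). Leaving out 1 library at a time ended these 4 calls in 8, 9, 5 and 8 of 12 cases, in the order named, with the direction kept. The broad libraries alone (4 against 6) gave 68 changed transcripts, 54 higher and 14 lower, and 8 of these were among the 16. With library sizes alone as the scaling, 277 were higher and 5 lower, and with the covariate 121 changed, 97 higher and 24 lower.

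Against the same Air Control libraries, DECe and DECe Gas Phase shared 9 changed transcripts in the same direction, the 3 above (psme_t031938, psme_t158514 and psme_t132144) and 6 more. Independent lists of these sizes would share 0.0117, and 8 simulations with unchanged groups shared 0. With the Air Control libraries split 3 and 3, the overlap was 0 to 1 over 10 splits. Across transcripts, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson correlation of 0.855, against 0.471 simulated with no effect and 0.751 on average with split controls. The covariance was 1.87 observed and 0.193 simulated. The simulations drew every library from a common profile, so they held no narrow libraries. DECe and DECe Gas Phase both hold narrow libraries and Air Control holds none, also with the controls split. The correlation and covariance above the simulated ones, and the correlation with split controls, can therefore not be told apart from library class. All 9 shared transcripts also changed in a fit of the 8 broad libraries of these groups against the 6 Air Control libraries. Their log2 fold changes there were 3.57 to 9.16 or, for the lower ones, -6.27 and -7.59 (edgeR adjusted p = 7.56e-04 to 0.0489). These values argue against narrow libraries as the source of the 9 calls, although the same broad libraries entered both fits.

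The fourth comparison addressed the CeO2 additive, with DECe set against DE. It gave 54 changed transcripts, 27 higher and 27 lower in DECe (edgeR, adjusted p under 0.05). On the higher side, psme_t037059 (1254 nt) was at 11.8 ± 13.1 CPM in DECe against 0.573 ± 0.715 CPM in DE (SD, n = 7 and 7), a log2 fold change of 3.70 ± 0.73 (SE, edgeR adjusted p = 0.0288). The 517 nt transcript psme_t097652 was at 18.6 ± 12.5 CPM against 1.51 ± 2.08 CPM (SD, n = 7 and 7), a log2 fold change of 3.49 ± 0.76 (SE, edgeR adjusted p = 0.0411). The floor of 3 counts was 1.06 CPM in DE replicate 12 and 3.91 to 7.19 CPM in the other narrow DE libraries. Some DECe levels, such as 3.54 CPM of psme_t037059 in DECe replicate 3, were not detectable in the latter. DE replicate 5, the broad one, was at 1.30 CPM of psme_t037059 and 0.358 CPM of psme_t097652. On the lower side, psme_t083038 (594 nt) was at 16.5 ± 38.2 CPM in DE (SD, n = 7) and had 1 count over all DECe libraries (edgeR adjusted p = 0.0491), and psme_t126558 (419 nt) was at 13.8 ± 11.1 CPM in DE (SD, n = 7) against 0.132 ± 0.347 CPM in DECe (SD, n = 7, edgeR adjusted p = 0.0446). The mean of psme_t083038 rests on DE replicate 4, at 103.04 CPM, with at most 4.57 CPM in each of the others. DE replicate 5 had 1 count of psme_t083038 and 0 counts of psme_t126558, so the DE levels of both rest on the narrow libraries. When 1 library was left out, the calls of psme_t037059, psme_t097652, psme_t083038 and psme_t126558 ended in 5 of 14, 8 of 14, 5 of 7 and 5 of 8 cases in which each was tested, and in 7 of 16, 7 of 18, 6 of 14 and 6 of 14 other alternatives. The count was 0 in the narrow libraries (3 against 6) and 0 with the covariate. It was 1 in the broad libraries (4 against 1), where the single DE library was assumed to vary like the other groups, so that value says little about the 54. In these fits 575, 3253 and 3649 transcripts had an unadjusted p under 0.05, in the order named. It also ran from 0 without DE replicate 6 to 414 without DE replicate 5, and under DESeq2's size factors the split was 28 higher and 157 lower.

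The fifth comparison addressed the particles, with whole DECe exhaust set against its filtered form. No transcript passed the threshold in the main edgeR fit, and 1147 of 26942 (4.26%) had an unadjusted p under 0.05. Some passed in edgeR with the replicate number as a block, although the numbers did not pair the libraries. Some also passed with library sizes alone, with only the 2 groups compared and without the dominant transcripts, as given below. The other tools called 3 (DESeq2), 12 (limma-voom with sample quality weights) and 0 (limma on log2(RPKM + 1)). The broad libraries alone also gave 0, with 5.42% at an unadjusted p under 0.05, as did the narrow ones, with 4.18%. The smallest p-values belonged to psme_t137885 (392 nt), at 0.00536 ± 0.0109 CPM in DECe and 0.423 ± 0.607 CPM in DECe Gas Phase (SD, n = 7 and 6, edgeR adjusted p = 0.0520), and on the other side to psme_t022430, at 1.28 ± 1.90 CPM in DECe and 0.0387 ± 0.0345 CPM in DECe Gas Phase (SD, n = 7 and 6, edgeR adjusted p = 0.109). Leaving out 1 library brought psme_t137885 past the threshold in 6 of 13 cases, with DECe replicate 2 or 4 or DECe Gas Phase replicate 2, 5, 7 or 10 left out (edgeR adjusted p = 0.0112 to 0.0456, against 2.53e-04 to 1 over its alternatives, of which 2 of 14 also passed). It brought psme_t022430 past the threshold in 1 of 13 cases, without DECe replicate 2 (edgeR adjusted p = 0.0209, against 0.0209 to 1 over its alternatives). In simulated data for this comparison, the test recovered 11% of transcripts changed 4-fold and 92% of those changed 16-fold, so a change of 4-fold would mostly have been missed. The simulated libraries shared 1 profile and the changed transcripts lay above a minimum mean count. In the real libraries larger changes could therefore be missed more often than simulated.

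Over the 4 groups together, 1382 transcripts changed (edgeR F test, adjusted p under 0.05), 114 with the broad libraries alone and 116 with the covariate. Group accounted for a share of 0.320 of the squared distances between libraries (R2, one-sided permutation test on distances, p = 0.00161), and for 0.249 among the broad libraries (p = 0.135). Between pairs of groups, R2 was 0.404 for DE and Air Control (exact permutation test, one-sided, p = 0.00583, adjusted p = 0.0291 over 5 pairs). It was 0.161 for DECe and Air Control (exact p = 0.0711, adjusted p = 0.0889), 0.121 for DECe Gas Phase and Air Control (exact p = 0.0238, adjusted p = 0.0534), 0.193 for DECe and DE (exact p = 0.0321, adjusted p = 0.0534) and 0.0700 for DECe and DECe Gas Phase (exact p = 0.488). Among the broad libraries, R2 was 0.154 for DECe and 0.148 for DECe Gas Phase against Air Control (exact p = 0.0333 and adjusted p = 0.05 for each). Library class, defined from the same counts, accounted for 41.0% of the squared distances over all 26 libraries, more than the 4 groups. On the first principal component Air Control ran from -206 to -191 and DE from -201 to 532. Such permutation tests respond to unequal spread as well, so their p-values do not separate it from a shift between groups.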

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

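The exact test of library class by group, the test with the covariate, the count of narrow libraries among exposed seedlings and the comparison of medians after thinning were chosen after their results were seen. The bounds for the splits of the libraries, the sign test, the length test and the extremes after thinning were set before theirs were seen.

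Samples far from the rest of their group were searched for in 20 groups of values for library measures and 32 for named transcripts, and 6 and 12 were found. Chance gives about 1 in 20 for independent and normally distributed values. The CPM values were skewed with many at 0, and the library measures depend on each other. The 6 and 12 can therefore not be set against that rate. In DE, replicate 5 stood apart on all 5 library measures. It had 28990156 counts (others 2467403 to 9017951), of which 17745686 lay outside the dominant transcripts (others 151321 to 684977), a dominant share of 38.8% (others 91.6% to 95.8%), 57063 detected transcripts (others 6049 to 21999) and a narrow marker share of 0.00792% (others 10.5% to 14.9%). DECe Gas Phase replicate 5 had a narrow marker share of 12.5% (others 0.0132% to 1.09%).

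Among the named transcripts, Air Control replicate 14 stood apart for psme_t132144 at 14.5 CPM (others 0.640 to 2.74) and psme_t158514 at 0.579 CPM (others 0.0982 to 0.247), and Air Control replicate 15 for psme_t094707 at 2.30 CPM (others 0.726 to 1.27). In DECe, replicate 2 was high for psme_t031938 at 31.1 CPM (others 0.576 to 8.26) and for psme_t030355 at 0.249 CPM (others up to 0.0974). Likewise replicate 13 was high for psme_t124074 at 6.87 CPM (others up to 2.75), replicate 5 for psme_t126558 at 0.918 CPM (others up to 0.00849), replicate 4 for psme_t137885 at 0.0290 CPM (others up to 0.00849) and replicate 3 for psme_t083038 at 0.00425 CPM, from 1 count (others 0). In DE, replicate 4 was at 103.04 CPM of psme_t083038 (others up to 4.57). In DECe Gas Phase, replicate 10 was at 0.120 CPM of psme_t132144 (others up to 0.0218) and replicate 3 at 1.61 CPM of psme_t137885 (others up to 0.460).

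The first pattern was the 2263 transcripts that differed between DE and Air Control. Of 40 splits of these libraries 1, the real one, gave as many and the highest other gave 118, which argues against chance. A share of 1 in 40 is the smallest that so many splits can show, so chance was not excluded. The narrow libraries are a candidate source. Within DECe and DECe Gas Phase, which hold no DE or Air Control library, 90.8% of the 2263 had the same sign in 5 narrow minus 8 broad libraries (93.7% of the higher and 87.7% of the lower ones), against 67.5% of all tested transcripts, and 804 changed there too. A bias by transcript length stays open, since the correlation of fold change and implied length across transcripts (Spearman 0.134) lay between the bounds set for and against it, while among the 2263 themselves it was -0.412, with a median length of 757 nt for the higher and 1548 nt for the lower ones. An effect of diesel exhaust cannot be told apart from library class, because DE has 1 broad library and Air Control has no narrow one, and with the covariate 26 of the 2263 remained.

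The second pattern was the place of the 11 narrow libraries. The exact test over the groups gave p = 0.0153, but classes and test were both chosen after this distribution was seen, so it does not exclude chance. A lower total depth was tested with every library thinned to 2467403 counts, and the test set beforehand left it open, since the lowest broad library (Air Control replicate 14, 22348 detected transcripts) was 1.14 times the highest narrow one (DECe Gas Phase replicate 4, 19674), between the bounds of 1 and 1.5. The medians, compared only after that was seen, were 33135 and 10714, a ratio of 3.09, which argues against depth as the whole difference between the classes. An effect of the exposures, with all 11 among the 20 exposed seedlings, cannot be told apart from an effect of chambers, sampling or library preparation, since each group had 1 chamber and the labels give no batch.

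The other counts were set against 40 splits each. The real count was the highest for DECe and Air Control (41, highest other 15), for DECe Gas Phase and Air Control (16, highest other 5) and over the 4 groups (1382, highest other 87). Each was reached by 1 split, the real one, which argues against chance there. No smaller share can be seen with 40 splits, and the shares were not adjusted for the number of counts tested, so chance was not excluded. For DECe and DE, 4 splits reached the real 54 and the highest other gave 849, many times the real count. Here the splits did not argue against chance, and it was not excluded. What made another split reach 849 was not tested. For DECe and DECe Gas Phase all 40 splits reached the real 0 and the highest other gave 38.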

How the results depend on the processing

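The broad, narrow, covariate, dominant-transcript, thinning and legacy=FALSE alternatives below were chosen after the data were examined, and where no cause is named the cause was not tested. Counts of changed transcripts follow for the alternatives that moved them by more than 1.5 times, with DE, DECe and DECe Gas Phase standing for their comparison with Air Control, and the main counts were 2263 (DE), 41 (DECe), 16 (DECe Gas Phase), 54 (DECe and DE), 0 (DECe and DECe Gas Phase) and 1382 (4 groups).

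DESeq2's size factors gave 185 for DECe and DE. Library sizes alone gave 566 for DECe, 282 for DECe Gas Phase, 91 for DECe and DE, 1 for DECe and DECe Gas Phase and 871 over the 4 groups. Without a filter on low counts there were 67 for DECe, 25 for DECe Gas Phase and 2772 over the 4 groups. A mean of at least 50 counts gave 1127 for DE, 36 for DECe Gas Phase, 97 for DECe and DE and 768 over the 4 groups, with fewer transcripts tested. DESeq2 gave 966 for DECe, 605 for DECe Gas Phase, 888 for DECe and DE, 3 for DECe and DECe Gas Phase and 2527 over the 4 groups. In limma-voom with sample quality weights there were 13013 for DE, 818 for DECe, 537 for DECe Gas Phase, 10631 for DECe and DE, 12 for DECe and DECe Gas Phase and 14878 over the 4 groups. The fit that is not robust gave 596 for DECe, 4 for DECe Gas Phase and 7 for DECe and DE. On log2(RPKM + 1) limma gave 20101 for DE, 115 for DECe, 25 for DECe Gas Phase, 433 for DECe and DE and 10046 over the 4 groups. On log2(RPKM + 0.1) it gave 24306, 71, 5, 6868, 1 and 18357 in the order of the main counts, and on log2(RPKM + 1) without a filter 15612 for DE, 167 for DECe, 51 for DECe Gas Phase, 0 for DECe and DE and 504 over the 4 groups. RPKM divides by totals that the dominant transcripts fill, and whether this moved the counts was not tested. Fitting only the 2 groups compared gave 26 for DECe, 0 for DECe and DE and 1 for DECe and DECe Gas Phase.

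The broad libraries alone gave 27 for DE, 68 for DECe Gas Phase, 1 for DECe and DE and 114 over the 4 groups, from 15 libraries. The narrow libraries alone gave 0 for DECe and DE and 28 over the 3 groups they hold. The covariate gave 31 for DE, 86 for DECe, 121 for DECe Gas Phase, 0 for DECe and DE and 116 over the 4 groups. Without the dominant transcripts there were 26 for DECe, 9 for DECe Gas Phase and 2 for DECe and DECe Gas Phase. Thinning the other counts to 151321 per library gave 804 for DE, 4 for DECe, 0 for DECe Gas Phase, 110 for DECe and DE and 660 over the 4 groups. With legacy=FALSE there were 4 for DECe, 0 for DECe Gas Phase and 104 for DECe and DE.

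The replicate number as a block gave 218 for DE, 19 for DECe, 33 for DECe Gas Phase, 75 for DECe and DE, 61 for DECe and DECe Gas Phase and 366 over the 4 groups. The numbers did not pair the libraries. The deviations of 18 pairs with the same number had a median correlation of -0.0715, 4 of the 18 were over 0.1, and 1 of 19 libraries correlated best with its own number.

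Leaving out 1 library at a time gave 1510 to 3127 for DE. For DECe it gave 2 (without Air Control replicate 14 or 8) to 59 (without DECe replicate 13), with 3, 5, 6 and 24 without Air Control replicates 11, 5, 15 and 3 and 14 without DECe replicate 4. For DECe Gas Phase it gave 1 (without Air Control replicate 3 or 5 or DECe Gas Phase replicate 2) to 79 (without DECe Gas Phase replicate 5), with 47 without DECe Gas Phase replicate 4, 2 without replicate 3 and 3, 7, 9 and 9 without Air Control replicates 11, 15 and 8 and DECe Gas Phase replicate 7. For DECe and DE it gave 0 (without DE replicate 6) to 414 (without DE replicate 5), with 362 without DE replicate 12, 210 and 158 without DECe replicates 5 and 10, 1 to 16 without DE replicates 2, 4, 1 and 8 and 2, 5, 29 and 33 without DECe replicates 13, 4, 15 and 3. It gave 0 to 4 (without DECe replicate 2) for DECe and DECe Gas Phase. Over the 4 groups it gave 560 (without DE replicate 2) to 2114 (without DECe Gas Phase replicate 5), with 568, 641 and 793 without DE replicates 6, 4 and 8 and 690, 694, 807, 818 and 885 without Air Control replicates 11, 5, 15, 8 and 14.

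For distances (permutation tests), DECe Gas Phase lost its unadjusted p under 0.05 with Spearman distances (R2 0.114, p = 0.0758), DESeq2's size factors (0.117, p = 0.0606), the 2000 most variable transcripts (0.132, p = 0.0736) and log2(RPKM + 1) (0.121, p = 0.203). Among the broad libraries the 4 groups lost it (0.249, permutation p = 0.135) and DECe gained it (0.154, exact p = 0.0333). Leaving out 1 library gave R2 of 0.291 to 0.398 over the 4 groups, 0.380 to 0.532 for DE, 0.147 to 0.201 for DECe (all 13 with p under 0.05), 0.113 to 0.153 for DECe Gas Phase (p over 0.05 without any of the 6 Air Control libraries), 0.170 to 0.281 for DECe and DE (p over 0.05 without DECe replicate 2, 3, 4 or 13 or DE replicate 4, 6 or 8) and 0.0622 to 0.118 for DECe and DECe Gas Phase.

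Of the named transcripts, psme_t132144 kept its call against Air Control for DECe in all 16 alternatives and all 13 leave-outs, and for DECe Gas Phase in 13 of 16 and 7 of 12. The calls of psme_t031938 held in 7 of 16 alternatives for each of the DECe and DECe Gas Phase comparisons. Those of psme_t158514 held in 9 of 16 for DECe and 7 of 16 for DECe Gas Phase, and that of psme_t022430 for DECe Gas Phase in 5 of 14. The broad libraries alone gave no value for psme_t133486 and psme_t029573, which had 0 counts in every broad DE and Air Control library. The 1 reversed value was psme_t021809 in limma-voom (log2 fold change 0.60 in DE). Tests of gene lists were not run, because identifiers are not paired with names. At the depth of the narrow libraries, a transcript under a floor of 0.690 to 7.19 CPM can be missed.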

Other observations

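The pooling of DECe with DECe Gas Phase and the restriction to broad libraries were chosen after the data were examined. The tests of the resulting pattern were set before their results were seen, except that the test of the folds under library sizes alone was added after the other results, and was parted by direction after its bound was missed for the lower transcripts.

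With the broad libraries alone, the 8 libraries exposed to the CeO2 fuel exhaust, whole or filtered, were set against the 6 Air Control libraries. Of 29980 tested transcripts, 313 changed, 159 higher and 154 lower in the exposed libraries (edgeR, adjusted p under 0.05), and 13.6% had an unadjusted p under 0.05. The count fell to 152, 166, 171, 198 and 204 without Air Control replicates 15, 11, 5, 14 and 8, and to 196 without DECe replicate 4. With library sizes alone as the scaling it was 122, 87 higher and 35 lower. The transcripts with the smallest p-values in each direction, singled out after their values were seen, were psme_t004745, at 5.16 ± 0.974 CPM in the exposed libraries and 18.7 ± 2.69 CPM in Air Control (SD, n = 8 and 6, edgeR adjusted p = 1.84e-04), and psme_t019343, at 16.6 ± 3.53 CPM and 2.83 ± 1.29 CPM (SD, n = 8 and 6, edgeR adjusted p = 5.31e-04). These CPM values were scaled within the libraries of this fit and are not comparable with those above. On this scale psme_t132144 was at 10.6 CPM in Air Control, against 3.53 CPM in the fit of all libraries. The 4 broad DECe libraries alone gave 57 changed transcripts and the 4 broad DECe Gas Phase libraries 68.

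The pattern was weighed against chance, depth and scaling. For all 3 counts 1 of 40 splits, the real one, reached the 313, the 57 and the 68, and the highest other gave 1, 2 and 0. These values argue against chance. The restriction and the pooling were chosen after the data were examined, and 40 splits can show no smaller share. Chance was therefore not excluded. A difference in depth between the groups would have removed the calls, but 89.1% of the 313 stayed with the count outside the dominant transcripts as a covariate. Whether the scaling decides which transcripts pass stays open. With DESeq2's size factors 97.4% stayed, but these moved the median log2 fold change of all tested transcripts from 0.0017 to 0.011 only and so were no test, and with library sizes alone, which moved it to 0.13, 30.0% (94 of 313) stayed, between the 10% and 50% set beforehand. The higher transcripts of the 313 had a median log2 fold change of 1.95 (SD 1.30, median SE 0.360) before and 2.05 (SD 1.32, median SE 0.482) with library sizes alone, and the lower ones -1.55 (SD 1.66, median SE 0.289) before and -1.32 (SD 1.37, median SE 0.423), so the calls ended with larger errors and, for the lower ones, smaller folds. In each direction 100% kept their direction by more than the shift of 0.13, the smallest at 0.81 and -0.59. The smallest folds before were already 0.699 and -0.695, since these transcripts were chosen by their calls. A shift of 0.13 could therefore hardly reverse them, and this result does not decide about the scaling. The bound asked also for a median beyond the shift by more than 1 SD, which the higher side met and the lower side missed. An effect of the scaling stays open on both sides. A difference from Air Control that the only broad DE library shares was asked of DE replicate 5, which took no part in the fit. For 69.0% of the 313 it lay on the exposed side of the midpoint between the group means, short of the 80% set beforehand, above the 7.24% to 29.7% of Air Control libraries left out in turn and within the 65.2% to 87.2% of exposed libraries left out in turn, so with 1 library this stays open. An effect of the exhaust is a hypothesis that remains open beside an effect of the Air Control chamber, which was not tested because each atmosphere had 1 chamber. The narrow marker share was 0.0132% to 1.09% in the exposed broad libraries and 0.0118% to 0.0503% in Air Control. A remaining difference in library composition, sampling or library preparation was not tested and stays open too.

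Besides the dominant transcripts, 684 transcripts that rose in DE lay more than 5 log2 units higher both in DE than in Air Control and in narrow than in broad libraries of DECe and DECe Gas Phase. Their median implied length was 546 nt, against 1901 nt over all tested transcripts. They took 1.68% to 4.21% of the counts in 10 of the narrow libraries, 0.0221% in DECe Gas Phase replicate 4, the other narrow library, and at most 0.0333% in Air Control. DECe Gas Phase replicate 3 had the highest share among the broad libraries, at 0.315%, with counts for 598 of the 684. These transcripts were chosen by their values, and no explanation was tested.

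Among the broad libraries, 105 transcripts with at least 2 CPM (of the counts outside the dominant transcripts) in the lower of a pair of libraries had over 90% of their CPM in that pair. In 42 of them the pair was DECe replicate 13 and DECe Gas Phase replicate 3, and the next most frequent pair had 6. Together the 42 took 1577 and 3025 CPM of the total counts in those libraries, and 2.58 to 21.6 CPM in the other broad ones. The pair belongs to different groups, and no explanation was tested.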
